A study of Mus musculus with 4 samples.

How the data were processed

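Single myeloid cells were purified by fluorescence-activated sorting from the brains of tumor-bearing mice (Balb/C athymic nude, strain CAnN.Cg-Foxn1nu/Crl) into 384-well plates and processed by a sequencing provider with the plate-based method cited in the labels. In this method each well has its own barcode, each transcript carries a unique molecular identifier (UMI), and synthetic ERCC spike-in RNA is added to each well. The 4 samples are 1 plate each: BMDM without WBRT, BMDM with WBRT, microglia without WBRT and microglia with WBRT, grouped by their titles. Per the labels, the genome build was GRCm38, and the aligner, the counter and the annotation are not given in the sources used here.

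The deposited values are estimated counts of transcripts per gene and well, without normalization. That they are corrected for UMIs that coincide by chance was read from the values. All nonzero values (100%) matched, within 0.0051, the correction for 4096 possible identifiers. The expected counts of the deposited tables were rounded to whole numbers only where a count interval or TMM factors were computed, and the observed UMIs before correction were recovered for thinning. Symbols were used as the files give them, and 4 list symbols were matched through synonyms in RefSeq's table for GRCm38.p6, which also gave gene positions. Of 368 list symbols, 27 were not found in the files. The value of 1 list member is not reported here.

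Wells were kept when they held at least 1000 counts from genes other than ERCC and mitochondrial ones and had an ERCC share under 50%. This kept 234, 262, 157 and 151 wells of 384, and 15 wells of microglia with WBRT were left out for their ERCC share alone. In these wells the median ratio of endogenous to ERCC counts was 13.2, 11.7, 13.5 and 2.27. Counts of a library were summed over wells and divided by all endogenous counts to give CPM. A count of 3 corresponds to 2.37, 1.19, 3.43 and 4.62 CPM in the 4 libraries and served as the floor for genes with 0 counts. The ribosomal RNA gene Rn45s had 16309, 16457, 3523 and 19716 CPM, and it and overlapping annotated features such as Mir5109 were not read as biology.

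Comparisons were BMDM over microglia without WBRT, the same with WBRT, WBRT over no WBRT in BMDM, and the same in microglia. With 1 library per group, no test across samples was made, and a fit of sort and WBRT as additive effects over the 4 libraries was not run. Each CPM has an exact Poisson interval, each fold the exact conditional interval of a ratio of Poisson counts, each share of wells an exact (Clopper-Pearson) binomial interval, and each list median an interval from 1000 Poisson redraws of its members' counts, all at 95%. These intervals cover counting error only and treat transcripts as independent, although transcripts of a well are not. The log2 ratio was taken on CPM + 5, which understates differences of low genes. A list median was placed among 10000 random lists of the same size, matched on mean CPM in 20 bins, as a description of these libraries. Poisson counts were simulated for each comparison over 15690 genes, with 200 genes of at least 50 CPM changed. Among genes of at least 50 CPM, intervals held the true fold for 95.2% to 95.6%. All changed genes came out in the right direction. This checks the computation only, since transcripts were drawn independently, with no plate difference beyond the set changes.

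Before the data were examined, 17 gene lists, 13 lists of other cell types, the cluster markers and the rule for named genes were fixed. Per comparison, the rule took the 12 highest and 12 lowest log2 ratios among genes of at least 100 CPM in 1 library, seen in at least 20% of wells of the higher library, with Poisson intervals that do not overlap, leaving out mitochondrial, ribosomal protein and numbered predicted genes. Up to 4 members of each list with the largest ratios, all identity genes and Cdkn1a and Mki67 could be named too, as could the 10 leading genes of each cluster. Wells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1) without cell cycle, mitochondrial and ribosomal protein genes. A cluster was named when at least 3 fixed markers of a type had at least a doubled CPM + 5 against all other wells and a UMI in at least 25% of its wells. The type was the one with most markers among the cluster's 10 leading genes. With none there, it was the type with the highest share of its measured markers enriched. Unresolved ties stayed unnamed, as did clusters of wells shallow for their library with no marker of the type among the leading genes. Clusters with a median Malat1 under 1000 CPM, a limit set after seeing the data, are called low-Malat1 clusters. No doublet caller was run, since 1 cell was sorted per well and wells are few. Shares of wells with a UMI were compared after each well was thinned to 1000 UMIs, which left out no wells.

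Alternatives fixed in advance were a minimum of 500 or 3000 counts per well, TMM factors, totals without mitochondrial and ribosomal protein genes, the mean of each well's CPM, list floors of 100 CPM or none, a pseudocount of 1, leaving out wells of other named classes, Leiden resolutions of 0.5 and 1.5, 15 components, observed UMIs and thinning to 3000. Alternatives added after seeing the data left out the low-Malat1 clusters, cluster 7 or 1 well with astrocyte genes, left out cluster 5 for the named genes of the microglia WBRT comparison, compared 1 cluster alone, or thinned every well to 1000 UMIs before the WBRT list medians were taken. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors only, which lay between 0.982 and 1.03.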

Results

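Brain metastasis draws macrophages from the blood into a tissue that already has its own resident macrophages, the microglia. Transcripts were counted in myeloid cells sorted into 384-well plates from the brains of athymic nude mice carrying lung cancer brain metastases. The 4 plates hold cells labelled BMDM (bone marrow-derived macrophages in the usage of the field) or microglia, taken without or with whole brain radiation therapy (WBRT). The WBRT label gives 5 fractions of 2 Gy and the term d3, whose starting point it does not state. Each of the 4 groups is 1 plate, and no animals are named, so there is no replicate, no test was made and every difference below is a difference between libraries. The plates without WBRT carry the tumor stage label small and those with WBRT the label not stratified, so stage, plate and treatment cannot be told apart. After filtering, 234 wells of BMDM without WBRT, 262 of BMDM with WBRT, 157 of microglia without WBRT and 151 of microglia with WBRT were kept. They held 1265842, 2513025, 874710 and 649107 transcripts in that order, with medians of 4388, 8894, 4789 and 2546 per well. The median spike-in (ERCC) share of counts was 7.04%, 7.86% and 6.92% in the first 3 libraries and 30.6% in microglia with WBRT. Values are pooled CPM of a library, intervals are 95% intervals that cover counting error only, and a list median is the median log2 ratio of CPM + 5 over the list's members of at least 20 CPM in 1 of the 2 libraries.

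The first comparison asked how the BMDM and microglia sorts of brains without WBRT differ. By the clusters described below, 29.9% of these BMDM wells were dendritic-cell-like, 23.5% monocyte-like and 37.6% unnamed. Folds of named genes were not computed without the dendritic-cell-like wells, so they describe the sort as a whole. BMDM identity and MHC class II genes were far higher in BMDM, and microglia identity genes were higher in microglia. Ccr2, the receptor through which monocytes follow the chemokine Ccl2 (chromosome 9, 124101918 to 124109140, GRCm38), stood at 389 CPM in BMDM and had 0 counts in microglia, a difference of at least 113-fold against a floor of 3 counts. The calcium-binding protein gene S100a11 stood at 648 CPM against 0 counts, at least 189-fold. Lsp1, an actin-binding protein of leukocytes, was 78.4-fold higher (35.8 to 214), Crip1 73.4-fold (33.6 to 201), Plbd1 76.0-fold (32.4 to 235) and Cytip 46.8-fold (25.3 to 98.1). In the other direction, the B cell chemoattractant Cxcl13 was 7.56-fold lower in BMDM (7.03 to 8.14), at 685 against 5176 CPM.

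All 15 members of the BMDM identity list were higher in BMDM, with a median log2 ratio of 3.34 (3.14 to 3.87), above all 10000 random lists matched on expression. Itga4, the integrin subunit that separates blood-derived from resident brain macrophages, stood at 258 CPM in BMDM and 29.7 CPM in microglia. All 14 measured members of the microglia identity list were lower in BMDM, with a median of -1.47 (-1.69 to -1.37), below all 10000 random lists. P2ry12, the purinergic receptor of resting microglia, stood at 90.1 against 336 CPM, Tmem119 was 4.45-fold lower (3.68 to 5.40), the secreted glycoprotein gene Olfml3 4.16-fold lower (3.51 to 4.94) and the transcription factor gene Sall1 stood at 27.7 against 121 CPM. The 7 measured MHC class II genes, which present antigen to helper T cells, were all higher in BMDM, with a median of 4.28 (4.09 to 4.56), and H2-Aa stood at 9307 against 390 CPM. MHC class I genes had a median of 0.69 (0.51 to 0.83; 0.20 with wells of other classes left out), with 9 of 12 higher, and genes of alternative activation one of 0.94 (0.65 to 1.26; 1.67 with wells of other classes left out), with 10 of 12 higher, among them the mannose receptor Mrc1 at 158 against 18.3 CPM. Dendritic cell genes moved with them: 7 of 7 were higher in BMDM, with a median of 3.57 (3.05 to 4.02), and Ccr7, the receptor that guides dendritic cells to lymph nodes, stood at 495 CPM against 7 counts. Border-associated macrophage genes were higher too, in 4 of 4 cases with a median of 2.12 (1.69 to 2.53).

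Microglia without WBRT had the higher levels of complement, lysosomal and cell cycle genes. The complement list had a median of -1.18 (-1.21 to -0.94), with 9 of 11 lower in BMDM, and C1qb, a chain of the first complement component, stood at 3168 against 7756 CPM. Phagocytosis and lysosome genes had a median of -0.84 (-0.88 to -0.75), with 13 of 15 lower, among them Grn at 2184 against 4699 CPM. S phase genes were lower in 14 of 14 cases, with a median of -0.71 (-1.02 to -0.56) that became -1.52 over the 3 members of at least 100 CPM. Rrm2, a subunit of the enzyme that makes deoxynucleotides, was 9.43-fold lower (5.70 to 16.4). G2/M genes had a median of -0.83 (-0.99 to -0.54), with 14 of 15 lower. Disease-associated microglia genes had a median of -0.57 (-0.65 to -0.42) with 11 of 18 lower, and immediate early genes one of -0.51 (-0.61 to -0.38) with 18 of 19 lower. The interferon list, at 0.25 (0.12 to 0.38), and checkpoint genes, at -0.19 (-0.37 to -0.03), lay closer to 0. Medians of 0.03 for p53 targets, -0.05 for glycolysis and -0.07 for lipid genes had intervals that held 0 and means of the other sign, and the 3 p53 targets of at least 100 CPM had a median of -0.62. The cytokine list, at -0.13 (-0.28 to -0.05), turned to 0.082 with TMM factors and to 0.29 without cluster 7, which is described below, and stood at -0.73 over its 12 members of at least 100 CPM.

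**Figure D1:**
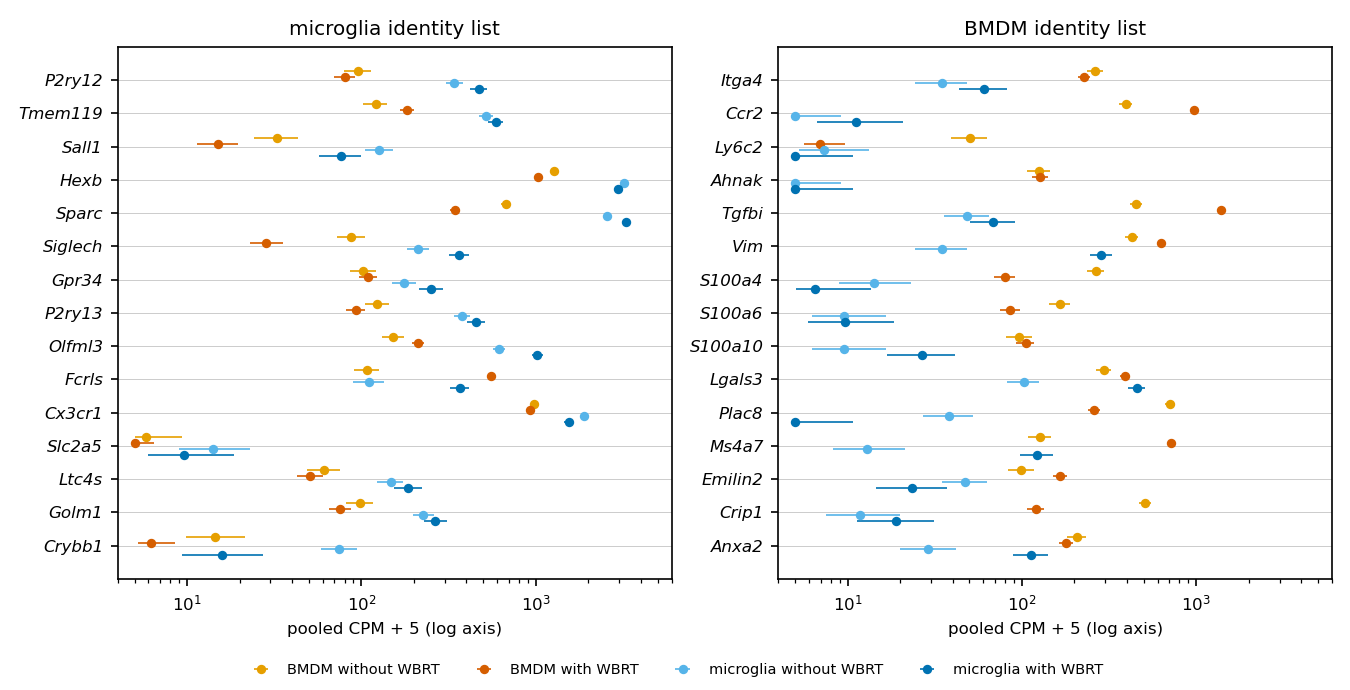
Pooled CPM + 5 on a log axis for each member of the microglia identity list (left) and the BMDM identity list (right), with 1 point per library and bars for the exact 95% Poisson interval. Ccr2 stands at 389 and 969 CPM in the BMDM libraries and at 0 and 6.16 CPM in the microglia libraries, and P2ry12 is higher in both microglia libraries.

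The same comparison after WBRT divided most identity genes in the same direction, with exceptions named below. Ccr2 was 157-fold higher in BMDM (61.4 to 578) and the monocyte gene Plac8 stood at 254 CPM against 0 counts, at least 55-fold. Of the MHC class II genes, H2-Eb1 was 60.7-fold (45.3 to 83.3) and the invariant chain Cd74 50.5-fold (42.1 to 61.7) higher. The MHC class II median was 4.57 (4.37 to 4.89), with 7 of 7 higher, and 5.31 in wells of at least 3000 counts. Tgfbi, an extracellular matrix protein of macrophages, was 22.0-fold higher (16.2 to 30.7). On the microglial side, Siglech was 15.2-fold lower in BMDM (11.4 to 20.6), the matrix protein gene Sparc 9.59-fold lower (8.85 to 10.4) and P2ry12 6.19-fold lower (5.14 to 7.46).

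The BMDM identity list had a median of 2.74 (2.45 to 3.19), with 13 of 14 higher, and the microglia identity list one of -1.87 (-2.18 to -1.70), with 12 of 13 lower. The exceptions were Lgals3, at 386 CPM in BMDM and 450 CPM in microglia, and Fcrls, at 551 and 361 CPM. Alternative activation genes had a median of 1.42 (1.23 to 1.62), with 11 of 14 higher, among them the angiogenic factor Vegfa at 262 against 21.6 CPM and the matrix glycoprotein Thbs1 at 179 against 7.70 CPM. Inflammatory cytokine genes were split, with 10 of 17 lower in BMDM and 7 higher, among the lower ones Tnf, 5.75-fold (5.10 to 6.50), and Il1a, 5.68-fold (4.78 to 6.81). Their median was -0.88 (-1.11 to -0.46) and their mean -0.31. That median became -0.01 when every well was weighted alike and -1.60 without the low-Malat1 clusters described below, where the median of alternative activation genes was 2.46. The interferon list had a median of 0.53 (0.29 to 0.72), which became 1.65 over its 7 members of at least 100 CPM, and Ifitm3, a membrane protein that blocks virus entry, stood at 727 against 78.6 CPM. MHC class I genes were higher in 11 of 11 cases, with a median of 0.45 (0.37 to 0.67). Complement genes had a median of -0.78 (-0.88 to -0.61), phagocytosis genes -0.31 (-0.35 to -0.14), S phase genes -0.52 (-0.73 to -0.28) and p53 targets -0.34 (-0.54 to -0.10). The disease-associated list, at -0.60 (-0.66 to -0.50), glycolysis, at -0.29 (-0.44 to -0.20), and immediate early genes, at -0.22 (-0.30 to -0.15), were less settled. Without the low-Malat1 clusters the first 2 became 0.30 and 0.41 and immediate early genes -0.93, and the latter became 0.46 with every well weighted alike. Medians of 0.23 for G2/M, 0.10 for lipid and -0.03 for checkpoint genes had intervals that held 0, the last 2 with means of the other sign, and the only G2/M gene of at least 100 CPM was lower, at -0.73. Dendritic cell genes were higher in BMDM in 3 of 3 cases, with a median of 2.73 (2.43 to 3.02), border-associated macrophage genes in 5 of 5 cases, with one of 2.43 (2.09 to 2.81), and astrocyte genes had a median of -3.56 (-3.95 to -3.03), largely from 1 well of the microglia plate.

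The next question was what differed after WBRT within the BMDM sort. In the library with WBRT, border-associated macrophage genes were higher, and dendritic cell and interferon response genes were lower. Pf4, the chemokine platelet factor 4 (chromosome 5, 90772435 to 90773383), was 16.4-fold higher (11.4 to 24.4), at 388 against 23.7 CPM. Cd93, a receptor in the clearance of dying cells, was 9.25-fold higher (7.33 to 11.8), the glycoprotein gene Gpnmb 8.49-fold (5.84 to 12.8), the coagulation factor subunit F13a1 6.40-fold (5.14 to 8.08) and the cytidine deaminase Apobec1 6.12-fold (5.31 to 7.09). Lysozyme genes were also higher, Lyz2 7.96-fold (6.86 to 9.30) and Lyz1 6.13-fold (5.85 to 6.42), although these near-identical neighbours on chromosome 10 may share reads. The chemokine gene Ccl5 was 251-fold lower (127 to 584), Ccr7 415-fold lower (141 to 2017, on 3 and 627 counts), the actin-bundling protein gene Fscn1 of mature dendritic cells 15.4-fold lower (12.8 to 18.7) and the surface antigen gene Ly6a 34.9-fold lower (23.5 to 54.0). Pf4, Cd93 and F13a1 are leading genes of cluster 3, described below, with 116 BMDM wells with WBRT and 1 without. Ccr7 leads cluster 10, with 0 and 36 wells. Folds of named genes in BMDM were not computed without these clusters. A change within cells and a different mix of wells therefore cannot be told apart for them.

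By list, 22 of 24 interferon response genes were lower with WBRT, with a median of -0.97 (-1.09 to -0.83) that lay below all 10000 random lists. Rsad2, an antiviral enzyme, stood at 20.7 against 194 CPM, Isg15 at 41.0 against 219 CPM and Ifit1 at 49.8 against 264 CPM. All 12 MHC class I genes were lower as well, with a median of -1.08 (-1.20 to -0.99), including the peptide transporter genes Tap1, at 58.1 against 179 CPM, and Tap2, at 16.3 against 78.2 CPM. All 13 measured genes of alternative activation and wound healing were higher, with a median of 1.46 (1.33 to 1.70), above all 10000 random lists. The scavenger receptor Stab1 stood at 568 against 137 CPM and the folate receptor Folr2 at 74.8 against 4.74 CPM. Within the monocyte-like cluster alone this median was 0.66. The list of border-associated macrophage genes moved with it, at 2.59 (2.32 to 2.90) with 5 of 5 higher, and shares Mrc1, Pf4, Cd163, F13a1 and Folr2 with it. Dendritic cell genes went the other way, at -2.16 (-2.36 to -1.76) with 6 of 7 lower.

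The p53 and DNA damage list had a median of 0.48 (0.17 to 0.65), with 7 of 10 higher, and 181 of the 10000 random lists were as high. Its cell cycle inhibitor Cdkn1a was 1.80-fold higher, at 1083 against 601 CPM, and 55.3% of wells thinned to 1000 transcripts held a Cdkn1a transcript against 41.0% (77.4% and 92.0% unthinned without and with WBRT). G2/M genes had a median of -0.75 (-0.95 to -0.34), with 5 of 9 lower and Top2a at 14.3 against 49.0 CPM, and 15 random lists were as low. This median became 0.20 when wells of microglia-like and dendritic-cell-like clusters were left out. S phase genes had a median of -0.32 (-0.63 to -0.14), which became 0.20 under the same change. The identity lists differed little, at 0.02 (-0.18 to 0.19) for BMDM, with a mean of the other sign, and -0.27 (-0.39 to -0.08) for microglia, which turned to 0.24 with every well thinned to 1000 UMIs. Yet the BMDM list held Ms4a7 at 715 against 122 CPM and Ly6c2, a marker of inflammatory monocytes, at 1.99 against 45.1 CPM. Ccr2 itself was 2.49-fold higher. Smaller medians were found for lipid (0.42, 0.26 to 0.57), glycolysis (0.26, 0.21 to 0.37), disease-associated microglia (0.21, 0.11 to 0.33) and phagocytosis genes (0.18, 0.14 to 0.25), the last 2 of which turned to -0.042 and -0.013 with wells of other classes left out. Checkpoint genes stood at -0.37 (-0.50 to -0.21; 0.11 over members of at least 100 CPM), with the ligand Cd274 at 16.7 against 64.8 CPM, and MHC class II genes at -0.16 (-0.29 to -0.13), which became 0.45 in the monocyte-like cluster. Immediate early genes stood at -0.10 (-0.14 to -0.03; 0.014 with every well weighted alike), complement at 0.07 (-0.03 to 0.28) and cytokines at 0.10 (0.02 to 0.16; -0.27 with wells of other classes left out), the last 2 with means below 0. Cluster 7, an unnamed cluster led by genes such as Kcnq1ot1, held 20.1% of wells without WBRT and 2.29% with WBRT. Without it, a choice made after seeing the data, interferon genes stood at -1.12, MHC class I genes at -1.30, MHC class II genes at -0.50, alternative activation genes at 1.66, lipid genes at 0.88, phagocytosis genes at 0.76, disease-associated microglia genes at 0.62, glycolysis at 0.53, complement at 0.43, BMDM identity at -0.32 and microglia identity at 0.25, the last with its sign turned.

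**Figure D2:**
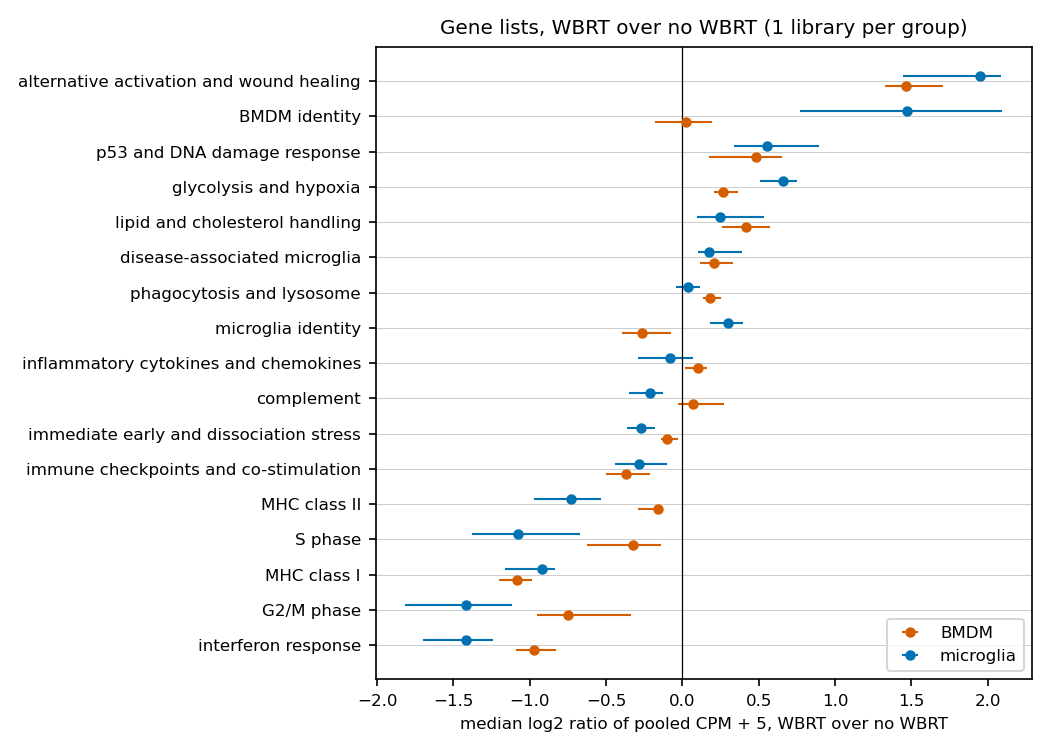
Median log2 ratio of pooled CPM + 5, WBRT over no WBRT, for 17 gene lists in BMDM and microglia, with bars for 95% counting intervals from redrawn counts and 1 library per group. The interferon list lies at -0.97 in BMDM and -1.42 in microglia, and alternative activation genes lie at 1.46 and 1.95.

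The last comparison placed microglia with WBRT against microglia without. Interferon response and cell cycle genes were lower, and genes of alternative activation were higher. Igf1, insulin-like growth factor 1 (chromosome 10, 87858265 to 87937047), stood at 285 CPM with WBRT and 2.29 CPM without, 125-fold higher (34.0 to 1037, on 185 and 2 counts). The iron exporter Slc40a1 was 8.61-fold higher (5.97 to 12.7), the fungal pattern receptor Clec7a 8.61-fold (6.12 to 12.4), Ms4a7 14.6-fold (6.77 to 37.6) and the glutathione transferase Gstm1 23.8-fold (12.2 to 53). Lpl, the lipoprotein lipase, stood at 884 against 88.1 CPM. The 49 wells of cluster 5, an unnamed cluster described below, held 19.7% of the transcripts of microglia with WBRT but 76.2% of the Igf1, 68.2% of the Slc40a1, 52.9% of the Lpl and 48.7% of the Ms4a7 counts. Without that cluster, a choice made after seeing the data, Igf1 stood at 84.5 CPM against 0 counts, Slc40a1 was 4.20-fold higher (2.65 to 6.81), Lpl 6.94-fold (5.28 to 9.28) and Ms4a7 9.15-fold (4.05 to 24.2), while Clec7a and Gstm1 were 9.81-fold (6.63 to 14.9) and 25.7-fold (12.6 to 60.7) higher. Ly6a was 125-fold lower (22.2 to 4982), on 1 and 169 counts, Ifitm3 10.8-fold lower (8.10 to 14.6), the interferon regulator Irf7 7.74-fold lower (5.24 to 11.9), and Ccl5 14.6-fold lower (10.3 to 21.2), and the antiviral gene Oasl2 stood at 38.5 against 268 CPM. Lyz2 and Lyz1, uncertain as a pair, were 12.2-fold (9.54 to 15.8) and 8.49-fold (7.67 to 9.43) higher.

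All 24 interferon response genes were lower with WBRT, with a median of -1.42 (-1.70 to -1.24), below all 10000 random lists. After thinning, Ifitm3 was seen in 6.62% of wells with WBRT (3.22% to 11.8%) and 59.9% without (51.8% to 67.6%), and the unthinned shares were 16.6% and 87.3%. This median was -1.12 without the low-Malat1 clusters and -2.20 within the microglia-like cluster of low Malat1 alone. All 12 MHC class I genes were lower, with a median of -0.92 (-1.16 to -0.83), and the light chain gene B2m stood at 2978 against 7610 CPM. G2/M genes had a median of -1.41 (-1.81 to -1.11), with 13 of 14 lower and Top2a, the topoisomerase of dividing cells, at 1.54 against 99.5 CPM. Only 2 G2/M genes reached 100 CPM, and their median was -0.44, while in the microglia-like cluster of low Malat1 the list stood at -2.34. S phase genes had a median of -1.08 (-1.38 to -0.67), with 12 of 14 lower and Mcm7, a subunit of the replicative helicase, at 16.9 against 125 CPM, and the 3 S phase genes of at least 100 CPM had a median of -2.56. In the complement list, at -0.21 (-0.35 to -0.13), Cfb and C4b had 13 counts each against 226 and 212 CPM.

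Alternative activation genes were higher in 11 of 13 cases, with a median of 1.95 (1.44 to 2.08), and fibronectin (Fn1) stood at 280 against 52.6 CPM. This median was 1.16 in wells of at least 3000 counts and 0.96 without the low-Malat1 clusters. Glycolysis and hypoxia genes had a median of 0.66 (0.51 to 0.75), with 12 of 16 higher and Egln3, an oxygen-sensing hydroxylase, at 81.7 against 10.3 CPM, and this became 0.0066 without those clusters. The p53 list had a median of 0.55 (0.34 to 0.90), with 10 of 11 higher, and 378 of the 10000 random lists were as high. Cdkn1a was 2.13-fold higher, at 1973 against 927 CPM, while the thinned share of wells with a Cdkn1a transcript was 50.3% with WBRT and 49.0% without (72.2% and 81.5% unthinned). Phlda3, another p53 target, stood at 24.6 against 4.57 CPM. The BMDM identity list was higher in 7 of 9 cases, with a median of 1.47 (0.77 to 2.09) that was 0.73 over all measured members and 2.60 over the 4 of at least 100 CPM, among them vimentin (Vim) 9.44-fold (6.23 to 14.8) and Lgals3 at 450 against 97.2 CPM, whereas Ccr2 stood at 6.16 CPM on 4 counts. Border-associated macrophage genes moved with it, at 2.18 (1.74 to 2.65). The microglia identity list stood at 0.30 (0.18 to 0.40), lipid genes at 0.24 (0.09 to 0.53; -0.10 in the microglia-like cluster of low Malat1) and disease-associated microglia genes at 0.17 (0.10 to 0.39; -0.078 without the low-Malat1 clusters). Of the disease-associated genes, 13 of 19 were higher and 6 lower, with a mean of 0.865. Igf1, Lpl and Clec7a, named above, are among the higher ones. MHC class II genes had a median of -0.73 (-0.97 to -0.54), with H2-Aa at 172 against 390 CPM, but went either way with the choice of wells, from -2.13 in wells of at least 3000 counts to 0.27 with every well thinned and 0.95 in the microglia-like cluster of low Malat1. Immediate early genes stood at -0.27 (-0.36 to -0.18; 0.26 without the low-Malat1 clusters) and cytokines at -0.08 (-0.29 to 0.07), which became -1.88 and -1.02 in the microglia-like cluster of low Malat1, checkpoint genes at -0.29 (-0.44 to -0.10; 0.0067 with every well thinned) and phagocytosis genes at 0.04 (-0.04 to 0.11). Alongside these lists, the median spike-in share was 30.6% with WBRT and 6.92% without, and low-Malat1 clusters held 73.5% and 38.9% of wells.

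Set side by side, the log2 ratios with WBRT in the 2 sorts, which share no library, were correlated across the 1450 genes of at least 100 CPM in 1 library of each sort (Pearson r = 0.575, Spearman rho = 0.520). Genes are not independent replicates, and this relation was not tested across samples. Genes lower in both sorts included Ly6a (-4.58 in BMDM and -4.92 in microglia), Ccl5 (-6.62 and -3.74), Isg15 (-2.28 and -1.94), Ifit1 (-2.30 and -1.65), Irf7 (-1.55 and -2.82) and Tap1 (-1.55 and -2.07). Genes higher in both included Igf1 (2.47 and 5.32), Ms4a7 (2.51 and 3.23), Ccl8 (2.47 and 2.62), Stab1 (2.02 and 2.05) and Fn1 (1.89 and 2.31). Igf1 and Ccl8 are leading genes of cluster 5, described below. With WBRT that cluster held 49 microglia and 20 BMDM wells, against 7 and 6 without. Cluster 8, also described below, held 31 and 19 against 0 and 2. The relation was not computed without these clusters, so wells of a shared kind may contribute to it. Isg15, Ifit1, Tap1, Ccl8, Stab1 and Fn1 were chosen here after their values were seen. The interferon difference was larger in microglia by a median of 0.21 over the same 24 genes (BMDM minus microglia, 0.03 to 0.56), and the G2/M difference by 1.12 over 8 genes (0.69 to 1.66). These differences between sorts were not tested and hold for the main settings. Over the alternatives, the interferon median ranged from -1.14 to -0.88 in BMDM and from -2.20 to -1.12 in microglia. The G2/M median ranged from -1.08 to 0.20 in BMDM and from -2.34 to -0.44 in microglia, so for both lists the ranges overlap.

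Clustering of the 804 wells gave 10 clusters, of which 7 could be named from markers fixed in advance. In microglia without WBRT, 93.0% of wells were microglia-like (87.8% to 96.5%), against 63.6% in microglia with WBRT (55.4% to 71.2%), and in the BMDM libraries 8.55% without WBRT (5.30% to 12.9%) and 9.54% with WBRT (6.27% to 13.8%). The order of the microglia plates turned at resolution 0.5, to 42.7% without and 95.4% with WBRT. The plates shared cluster 1, of low Malat1, with 54 microglia wells without WBRT and 62 with WBRT, but not the other microglia-like clusters: cluster 4, led by Kcnk2, Ccl4 and Rrm2, held 92 wells without WBRT and 3 with WBRT, and cluster 8, led by Adamts1, the heat shock gene Hspa1a and Tnf, held 0 and 31. Monocyte-like wells with Ccr2, Plac8 and Ms4a4c made up 23.5% of BMDM without WBRT (18.2% to 29.5%) and 24.8% with WBRT (19.7% to 30.5%), but in 4 of 6 other clusterings no cluster took this name (resolution 0.5, wells of at least 3000 counts, 15 principal components and observed UMIs), and only a cluster of 9 wells took it at resolution 1.5. Dendritic-cell-like wells made up 29.9% without WBRT (24.1% to 36.2%) and 1.91% with WBRT (0.622% to 4.40%), in a cluster led by Xcr1, Itgae and Clec9a and another led by Ccr7, Cacnb3 and Ccl22. These shares ranged with the settings from 15.4% to 50.3% without WBRT and up to 12.8% with WBRT. Outside cluster 3 the dendritic-cell-like wells were 70 of 233 and 5 of 146 wells. Without reference to clusters, 19.2% of thinned BMDM wells without WBRT held a Ccr7 transcript (14.4% to 24.9%) and 0 of 262 with WBRT, which allows up to 1.40% of wells with such a transcript at this depth and does not limit the cells that express Ccr7, where microglia gave 0.637% and 0 of 151 wells. The shares in BMDM were 22.4% and 0.433% with wells thinned to 3000 UMIs and 32.9% and 0.382% unthinned. Cluster 3, border-associated-macrophage-like with Pf4, F13a1, Cbr2 and Mrc1, held 116 wells of BMDM with WBRT and 1 well of each other library, so it may be that library and not a type. Its name is uncertain as well: after thinning, 47.9% of its wells held a Ccr2 transcript (85.7% unthinned), against 58.7% of monocyte-like wells (80.2% unthinned), and among wells of at least 3000 counts the largest cluster, of 117 wells, was macrophage-like and a border-associated-macrophage-like one held 46 wells. Cluster 6, unnamed and led by Cd7 and Cd209a, held 35 BMDM wells without WBRT and 25 with WBRT. Cd209a is a fixed dendritic cell marker, so dendritic cells may lie there too. The main shares of dendritic-cell-like wells cover clusters 9 and 10 only. Cluster 7, unnamed, held 47 (20.1%, 15.1% to 25.8%) and 6 (2.29%, 0.845% to 4.92%). Cluster 7 was led by genes of no fixed list such as Vmn2r55, Grk4 and the noncoding RNA Kcnq1ot1, the last at a mean of 40690 CPM against 2911 CPM in other wells. Its wells had a median of 5790 counts and a median spike-in share of 4.74%. Whether a cell type or the quality of the RNA sets these wells apart was not tested, so the cluster was not read as a population of cells. The sort gates are not given in the labels and could set any of these shares.

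**Figure D3:**
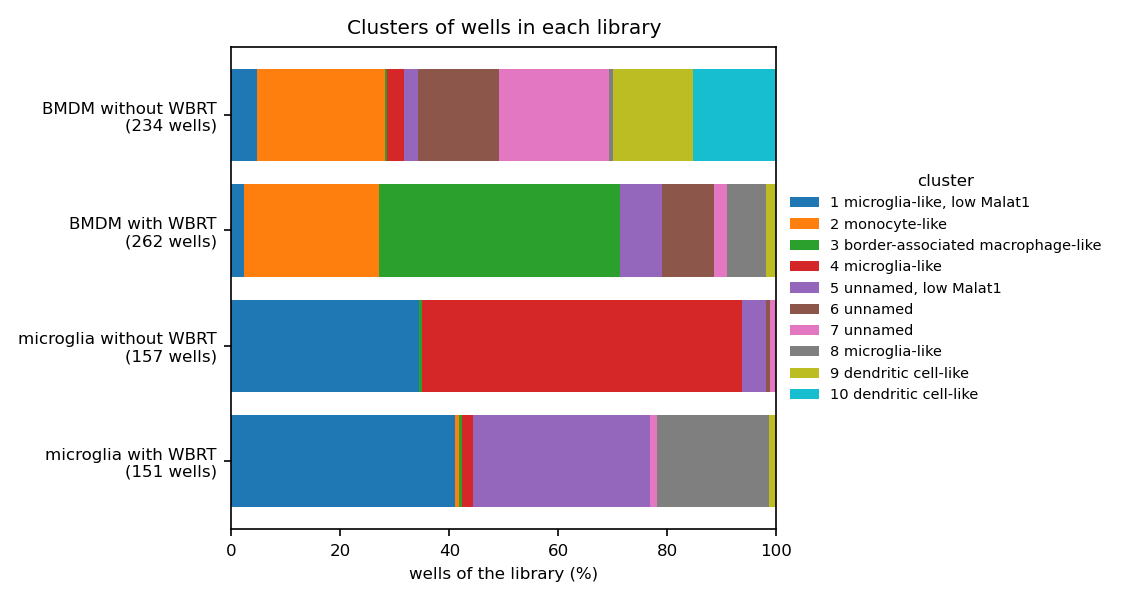
Share of each library's wells (percent) in 10 clusters, with 1 bar per library and clusters named from fixed markers where 3 or more were enriched. Cluster 3 makes up 44.3% of BMDM with WBRT, and clusters 1 and 5, of low Malat1, make up 73.5% of microglia with WBRT.

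Clusters 1 and 5 stood apart by their RNA. Malat1, an abundant nuclear RNA, had a median of 210 CPM in cluster 1 and 309 CPM in cluster 5, against 2236 CPM or more in the other clusters, and their median spike-in shares were 22.4% and 26.5%. Together they held 7.26% of BMDM wells without WBRT (4.29% to 11.4%), 9.92% with WBRT (6.59% to 14.2%), 38.9% of microglia wells without WBRT (31.2% to 46.9%) and 73.5% with WBRT (65.7% to 80.4%). Cluster 1 was microglia-like, led by Sparc, Olfml3 and Cxcl13. Cluster 5 stayed unnamed and was led by the iron exporter Slc40a1, Ccl8, Igf1, the heme-degrading enzyme Hmox1 and Lpl, with 49 wells from microglia with WBRT, 20 from BMDM with WBRT, 7 from microglia without WBRT and 6 from BMDM without WBRT.

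**Figure D4:**
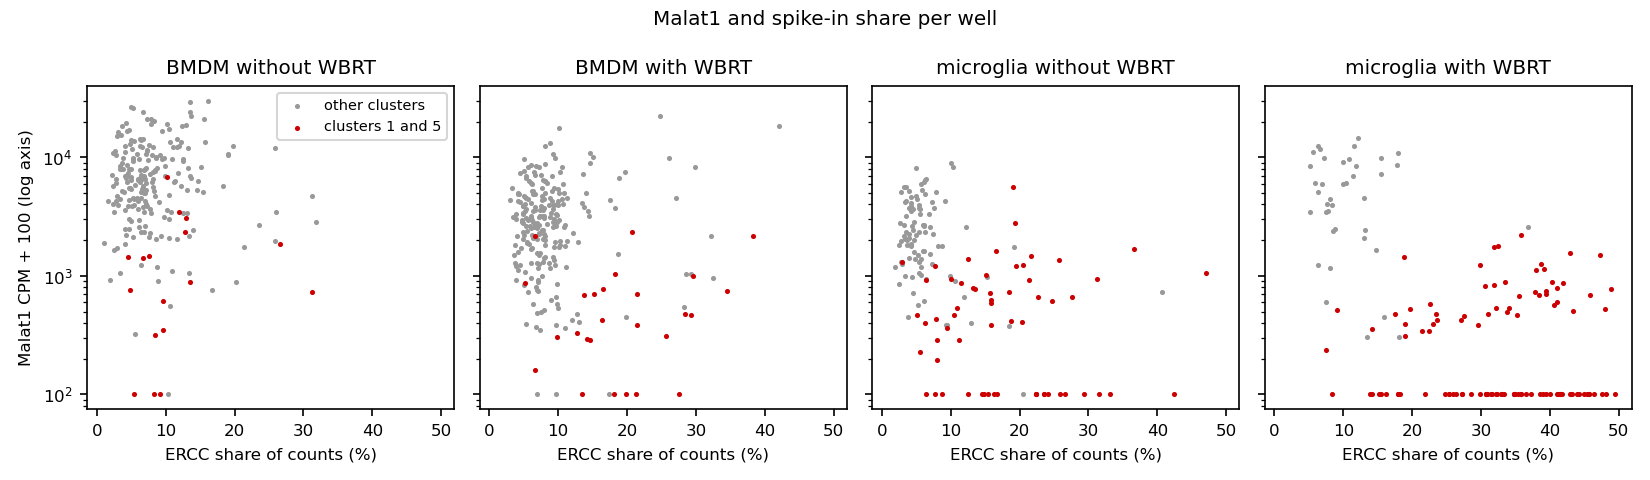
Malat1 CPM + 100 on a log axis against the ERCC share of counts (percent), with 1 point per well, 1 panel per library and wells of clusters 1 and 5 in red. In microglia with WBRT the red wells are 73.5% of the wells and lie at the higher spike-in shares.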

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

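The tests without low-Malat1 wells, without cluster 7, within the monocyte-like cluster, of libraries per group, of thinned Malat1 and of other nuclear RNAs were chosen after the results they bear on were seen, as was the test at matched depth, of which only the outcome was unseen when it was set, and the list of other nuclear RNAs was shortened after its totals per library were seen, so both forms of it are given.

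A pair of results went in opposite directions with WBRT in the 2 sorts, a difference that was not tested. The microglia identity list was lower in BMDM and higher in microglia, by -0.42 as the median of BMDM minus microglia (-0.67 to -0.21), and its sign in BMDM turned with every well weighted alike (0.053), over members of at least 100 CPM (0.014), without cluster 7 (0.25) and with every well thinned to 1000 UMIs (0.24). Serpinb9, an inhibitor of granzyme B, had log2 ratios of -3.18 in BMDM and 1.80 in microglia, which differ by -4.98, on 21 and 5 counts in microglia. The interferon list was also computed in wells left out of the comparisons for few counts or a high spike-in share, with at least 100 counts. There it had a median of -1.95 with WBRT in BMDM (-3.06 to -0.97, 65 wells with WBRT and 69 without) and -2.08 in microglia (-3.04 to -1.58, 128 and 99 wells). These wells lie on the same plates as the kept wells, so they are not independent of them and do not separate WBRT from plate.

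The lower interferon list with WBRT in both sorts might reflect the makeup of the plates rather than the state of cells. A larger share of low-Malat1 wells was argued against as the whole cause, since the median in microglia without those clusters was -1.12 (-1.46 to -0.92; 24 of 24 genes lower; 40 wells with WBRT and 96 without). A different mix of clusters in BMDM, such as the smaller share of dendritic-cell-like wells, was argued against as the whole cause only. The median within the cluster named monocyte-like, a name that 4 of 6 other clusterings did not give, was -1.04 (-1.29 to -0.84, 22 of 24 lower, 65 wells with WBRT and 55 without). That cluster held 24.8% of BMDM wells with WBRT and 23.5% without. How much the mix of the remaining wells adds to the plate-wide median was not tested. Irradiation, the tumor stage label and the plate cannot be told apart with 1 library per group, so an effect of WBRT on interferon signalling, or a stronger interferon state in brains with small tumors, stays a hypothesis.

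The larger share of low-Malat1 wells in the WBRT microglia plate, 73.5% against 38.9%, could come from shallow counts, from cells that lost nuclear RNA, or from a state of the cells. Shallow counts stay open: among wells of 1000 to 3000 counts these clusters held 95.5% with WBRT (88.8% to 98.7%; 84 of 88 wells) and 81.5% without (68.6% to 90.7%; 44 of 54 wells), and a ratio of thinned Malat1 CPM of 0.149 (0.117 to 0.188) decides nothing, since the clusters were called by their Malat1 and thinning leaves pooled CPM alike. Other nuclear RNAs (Neat1, Tug1, Meg3, Miat and Snhg11 together) were lower too, at 78.5 against 240 CPM, a ratio of 0.328 (0.225 to 0.464; 37 and 252 counts), and the longer first list (8 of its 10 RNAs measured) gave 0.268 (0.212 to 0.335), which is consistent with less nuclear RNA in these wells. Whether irradiation, the plate or the sort gave more such wells stays open, and the glycolysis list, whose median was 0.0066 without them, is best read with that in mind. Malat1 itself, pooled over kept microglia wells so that deep wells weigh most, was higher with WBRT, at 2999 against 2114 CPM.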

How the results depend on the processing

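No paired analysis was made, since each group is 1 library and the labels pair no animals, and no result comes from a test. Leaving out low-Malat1 clusters, cluster 7, cluster 5 for the named genes of microglia or the astrocyte-gene well, comparing 1 cluster alone and thinning every well to 1000 UMIs were chosen after seeing the data. The identity medians between the sorts kept their direction under each of 11 alternatives without and 12 with WBRT, and the interferon and p53 medians with WBRT over none under each of 13 in BMDM and 14 in microglia. For the identity medians, leaving out wells of other classes decides nothing, since classes were named from markers shared with the identity lists. Given here, with the cause not tested, are the values of identity medians between the sorts, of p53, interferon and G2/M medians with WBRT over none and of cluster shares that left their counting intervals, and every list median whose interval excluded 0 and that changed sign. Of the other medians, further ones left their intervals, with the same sign or from an interval that held 0. By count these were most with wells of other classes left out (21) and with every well weighted alike (20). Comparing 1 cluster alone, tried for the WBRT comparisons only and so on fewer medians, gave 13. With 3000 counts per well, the microglia identity median without WBRT was -1.34, microglia-like wells were 5.23% of BMDM without WBRT and 53.6% of microglia with WBRT, dendritic-cell-like wells were 50.3% and 12.8% of BMDM without and with WBRT, and, with WBRT over none, cytokines in BMDM stood at -0.10 and immediate early genes in microglia at 0.026. With 500 counts, dendritic-cell-like wells were 15.4% of BMDM without WBRT. At resolution 0.5, dendritic-cell-like wells were 47.0% and 11.1% of BMDM without and with WBRT, and microglia-like wells were 17.2% of BMDM with WBRT and 42.7% and 95.4% of microglia without and with WBRT, so the order of the microglia plates turned. With every well weighted alike, the microglia identity medians were -1.83 without and -1.67 with WBRT; BMDM over microglia, cytokines without WBRT stood at 0.41 and immediate early genes with WBRT at 0.46; and with WBRT over none, microglia identity in BMDM stood at 0.053, immediate early genes in BMDM at 0.014 and MHC class II in microglia at 0.039. Over all measured members, the microglia identity median without WBRT was -1.33 and cytokines stood at 0.21 (BMDM over microglia without WBRT) and -0.17 (WBRT in BMDM). At a floor of 100 CPM, the microglia identity median without WBRT was -1.33, and with WBRT over none p53 stood at 0.66 in BMDM and 1.09 in microglia, interferon at -1.13 and -1.94, G2/M in microglia at -0.44, and in BMDM microglia identity at 0.014, S phase at 0.21, cytokines at -0.039 and checkpoints at 0.11. TMM factors turned cytokines without WBRT to 0.082, and totals without mitochondrial and ribosomal protein genes turned cytokines to 0.13 there and to -0.11 with WBRT in BMDM. With wells of other classes left out, the microglia identity median with WBRT was -2.43, and with WBRT over none in BMDM G2/M stood at 0.20, S phase at 0.20, disease-associated genes at -0.042, cytokines at -0.27 and phagocytosis at -0.013. Without low-Malat1 clusters, the identity medians with WBRT were -2.30 for microglia and 3.27 for BMDM, disease-associated genes stood at 0.30 and glycolysis at 0.41 with WBRT (BMDM over microglia), and with WBRT over none in microglia p53 stood at 0.93, interferon at -1.12, G2/M at -0.95, disease-associated genes at -0.078 and immediate early genes at 0.26. Without cluster 7, the microglia identity median without WBRT was -1.99, cytokines stood at 0.29 there, and with WBRT over none in BMDM interferon stood at -1.12 and microglia identity at 0.25. In 1 cluster alone, G2/M stood at -1.08 in BMDM and -2.34 in microglia, interferon in microglia at -2.20, MHC class II at 0.45 in BMDM and 0.95 in microglia, cytokines in BMDM at -0.30 and lipid genes in microglia at -0.10. With every well thinned, interferon stood at -1.14 in BMDM and -1.93 in microglia, G2/M in BMDM at -0.26, microglia identity and immediate early genes in BMDM at 0.24 and 0.0032, and MHC class II and checkpoints in microglia at 0.27 and 0.0067. Depth limits the microglia with WBRT most, where 1 count is worth the most CPM and 56 wells reach 3000 counts.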

Other observations

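The tests of cluster 5 were set before their results were seen, and the removal of the astrocyte-gene well was chosen after seeing the data.

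Other brain and blood cells left few transcripts. Summed neuron genes reached 1.58 to 7.70 CPM per library, fibroblast and pericyte genes 0.790 to 18.5 CPM, B cell genes 1.54 to 17.1 CPM, T cell genes 5.72 to 33.2 CPM and epithelial tumor genes 0 to 11.1 CPM, the last matched to mouse genes only. Endothelial genes gave 55.5 to 60.8 CPM, with Pecam1, which myeloid cells also express, the highest, neutrophil genes 187 to 342 CPM, mainly Csf3r and Cxcr2, and oligodendrocyte genes 85.7 to 182 CPM, with Cnp the highest. Natural killer genes stood at 236 CPM in BMDM without WBRT against 19.9 CPM with WBRT, mostly Klrk1, and at 26.3 CPM and 0 counts in microglia. In BMDM without WBRT, Klrk1 was seen in 39.7% of wells, but only 13 wells held at least 5 counts of the list. The sum therefore need not come from natural killer cells. Erythroid genes were seen mainly in 1 well of microglia with WBRT, at 94.5 CPM over the library. Astrocyte genes summed to 983 CPM in microglia with WBRT and to 33.2 to 101 CPM elsewhere. Of these, 1 well held 269 of 303 Slc1a3, 156 of 181 Aldoc and 43 of 44 Aqp4 counts, and the list median against microglia without WBRT was 3.32 with that well and 0.75 without it, over 7 and 2 genes.

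The higher BMDM identity list in microglia with WBRT prompted the hypothesis that macrophages may lie among the wells of cluster 5. Within that plate, the 49 wells of cluster 5 had a BMDM identity median of 1.62 against the other 102 wells (1.18 to 2.03; 7 of 9 genes higher). Their microglia identity median of -1.74 (-1.99 to -1.30) decides nothing, since 96 of the other 102 wells lie in clusters named from that list, so the hypothesis stays open. These wells did not account for the whole difference, since without cluster 5 the median with WBRT over none was still 1.15 (0.76 to 1.51; 8 genes). Microglia that lost identity genes are not excluded, and Ccr2, at 6.16 CPM in this library, gives no sign of fresh monocytes.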
